A study of Bos taurus with 30 samples.

How the data were processed

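RNA was measured in cervical tissue of 30 Limousin heifers, 1 library per heifer, taken at slaughter at 6 stages around oestrus. Per the labels' protocols, polyadenylated RNA was sequenced as single reads by the standard Illumina procedure. The submitters' processing notes name CASAVA version 1.0, Illumina software for processing sequence data. The aligner, counting program, genome build, annotation release and strand setting were not given in the sources used here. The deposited values are raw counts per Ensembl bovine transcript ID, and the authors' counts were used without further scaling of the deposited numbers. Each library lists the same 28054 IDs, of which 22621 had a count in at least 1 heifer.

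The deposited tables do not pair transcript IDs with gene names, and the name table used here matched 0 of the IDs. Results are therefore given for transcripts, and no gene symbol, pathway or cell type is named. The lists of genes, the 25-gene panel and the cell type markers fixed before the data were examined could not be applied. The rule for naming features then fell back on its last part, at most 2 IDs that rose and 2 that fell. These 4 IDs were chosen after their values were seen: the 2 with the smallest p in the 6-stage test among those highest 12 h after removal of the progesterone device, and the 2 with the smallest p among those highest at oestrus, each with a mean of at least 5 CPM. Counts were given per transcript, so reads shared between isoforms or near-identical copies could enter several IDs or be divided among them. Counts of 1451 IDs with a count equalled those of another ID in all 30 heifers, 48 of them among the IDs tested. With no strand setting known, overlapping and antisense transcripts were not told apart.

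Groups followed the stage in each sample's labels: CIDR+12h (n = 6), CIDR+24h (n = 6), Oestrus (n = 4), Oestrus+12h (n = 4), Oestrus+48h (n = 5) and Luteal (n = 5). The protocol text in the labels gives 5 heifers for Oestrus+12h and 4 for Oestrus+48h, the reverse of the sample labels, and the sample labels were kept. Replicates were separate heifers and were numbered in accession order within a stage. No 2 libraries of a stage agreed within sampling noise, since the smallest chi-square per degree of freedom between any pair was 19.32.

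Library totals ranged from 5434853 to 19628122 counts, with a median of 7983022. The 16940 transcripts kept by edgeR's filterByExpr (minimum count 10, minimum total 15, by stage) held 99.93% of the counts. Counts were normalised with TMM factors and fitted in 1 quasi-likelihood model over all 30 heifers with edgeR 4.0.16 in R 4.3.3 (robust, 1 mean per stage). A transcript was called when its Benjamini-Hochberg adjusted p lay under 0.05. One test asked for any difference among the 6 stages and 7 tests compared a pair of stages. The biological coefficient of variation was 0.468. CPM values are counts scaled to a common library size with TMM factors, and log2 CPM used a prior count of 2. Standard errors of log2 fold changes were obtained from the fold change and the F statistic.

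Distances between heifers on log2 CPM were split by the 6 stages with the permutational test adonis2 (vegan 2.7.1), using 9999 permutations. For pairs of stages the same share was computed directly for every split of their heifers. Where the 2 stages had equal numbers, a split and its mirror were both counted. The tests were tried on simulated counts with 200 changed transcripts drawn at the real means and library sizes. Between 56.5% and 80.6% of 4-fold changes were recovered over the 7 comparisons, and between 11.6% and 40.6% of 2-fold changes. Each transcript was drawn independently of the others, so differences that a heifer carries across many transcripts were absent. Recovery in the real data could therefore differ from these shares. Each count of calls was also computed for other splits of the same heifers, up to 100 per test with the real one included.

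Alternatives chosen before the data were examined were size factors of the kind DESeq2 uses, upper-quartile factors, DESeq2 1.42.0, no count filter, a filter of at least 10 CPM in at least 4 heifers, limma 3.58.1 voom with sample quality weights, 1 surrogate variable (sva 3.50.0), a fit without the 3 heifers with 2 digits before the hyphen in their animal number, a fit of only the stages compared, and leaving out in turn each heifer of the stages compared. A stage-wise test, voom without weights, 2 to 6 surrogate variables and, for pairs, leaving out heifers of the other stages were added after seeing the data. So was an exact count, over all splits of a pair's heifers, of transcripts whose groups did not overlap. The test of distances and the principal components were also not among the planned tests.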

Results

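Transcript levels were measured in the cervix of 30 Limousin heifers at 6 stages of a synchronised cycle. The heifers carried a controlled internal drug release (CIDR) device with 1.94 g progesterone in the vagina for 8 days and received 0.5 mg of a prostaglandin F2α analogue 1 day before its removal. Tissue was taken 12 h after removal (CIDR+12h, 6 heifers), 24 h after removal (CIDR+24h, 6 heifers), at onset of oestrus (Oestrus, 4 heifers), 12 h later (Oestrus+12h, 4 heifers), 48 h later (Oestrus+48h, 5 heifers) and on day 7 after onset (Luteal, 5 heifers). The protocol text gives 5 heifers for Oestrus+12h and 4 for Oestrus+48h. Library totals were 11473218 ± 4076695 counts at CIDR+12h (SD, n = 6), 7322750 ± 914866 at CIDR+24h (n = 6), 7389981 ± 1707138 at Oestrus (n = 4), 6978520 ± 1134248 at Oestrus+12h (n = 4), 9986678 ± 3847615 at Oestrus+48h (n = 5) and 8410614 ± 498808 at Luteal (n = 5). Between 18256 and 19813 transcripts had a count in a heifer. The 10 most abundant transcripts took from 6.87% to 23.6% of a library.

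The clearest stage profile was a group of transcripts with higher levels 12 h after CIDR removal than at oestrus and later. In the 6-stage test, 39 of 16940 transcripts passed, and 31 of them had their highest mean at CIDR+12h. As many passed in 8 of 100 splits of the heifers, the real one included, with 2946 in the highest other. The median level of these 31 transcripts was 15.2 ± 14.8 CPM at CIDR+12h (SD, n = 6) and lay between 7.03 and 45.2 CPM in each of those heifers. It was 0.624 ± 0.255 CPM at Oestrus (n = 4), 0.448 ± 0.13 at Oestrus+12h (n = 4), 0.622 ± 0.0851 at Oestrus+48h (n = 5) and 0.476 ± 0.0649 at Luteal (n = 5). At CIDR+24h, 1 heifer (replicate 4) had a median of 46.1 CPM, while the other 5 lay between 0.423 and 0.898 CPM. In 30 of the 31 transcripts, every CIDR+12h heifer lay above those 5 and above every heifer of the later stages. The transcripts were chosen by the same test, so these levels describe the set and are no separate evidence for it.

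**Figure D1:**
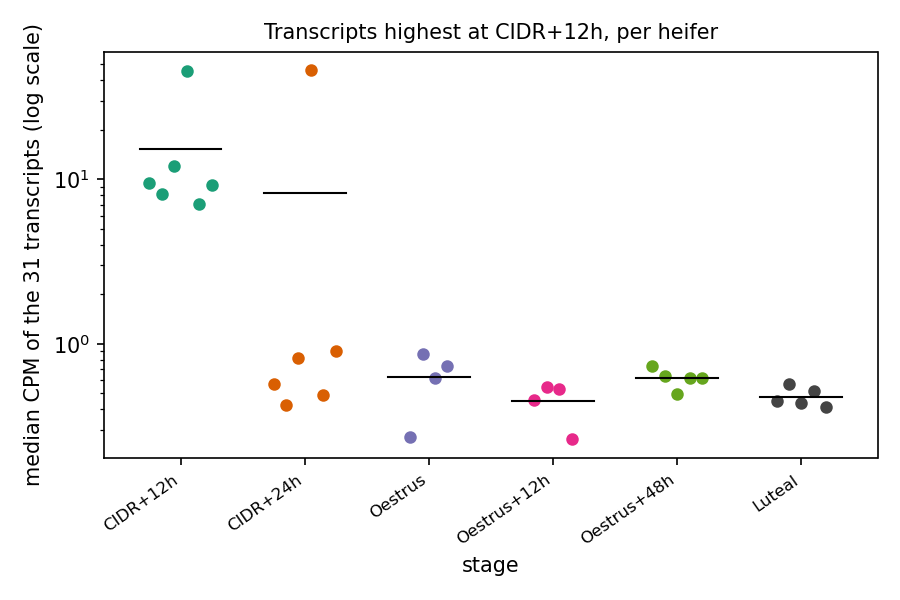
Median CPM of the 31 transcripts with their highest mean at CIDR+12h, per heifer (points) and stage (x axis), on a log y axis, with a line at each stage mean. The 6 CIDR+12h heifers lie between 7.03 and 45.2 CPM, CIDR+24h replicate 4 lies at 46.1 CPM, and no other heifer is above 0.898 CPM.

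Of the other transcripts that passed, 5 were highest at CIDR+24h and 3 at Oestrus, and none was highest at Oestrus+12h, Oestrus+48h or Luteal. In 4 of the 5 highest at CIDR+24h, CIDR+24h replicate 6 was the highest heifer, and 4 of the 39 had over 50% of their summed CPM in a single heifer. In 30 of the 31 highest at CIDR+12h, the highest heifer was CIDR+24h replicate 4 or CIDR+12h replicate 4. A correlation over 0.99 with another passing transcript was found for 4 of the 39. The 39 are therefore not all separate signals, and how many are was not tested. The smallest adjusted p in the 6-stage test was 0.0122 (edgeR). The count depended on single heifers: 6 transcripts passed without CIDR+12h replicate 4 and 119 without CIDR+24h replicate 4. Without the 3 heifers whose animal number has 2 digits before the hyphen, 0 passed, although the log2 differences of the transcripts ENSBTAT00000025270 and ENSBTAT00000020473 between CIDR+12h and Luteal were 6.85 and 5.00 in that fit, against 6.70 and 4.91 with all heifers. Their edgeR adjusted p in the 6-stage test was then 0.0615 for each. These 3 heifers are 2 of the 4 at Oestrus and 1 at CIDR+12h, and whether they came from another herd or batch is not given in the sources used here.

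The question of how the cervix differed between 24 h and 12 h after CIDR removal was addressed by comparing CIDR+24h with CIDR+12h. The transcript ENSBTAT00000025270 had 22.5 ± 19.5 CPM at CIDR+12h (SD, n = 6) and 11.9 ± 27.7 CPM at CIDR+24h (n = 6), where it ranged from 0.163 to 68.5 CPM. ENSBTAT00000020473 had 17.7 ± 13.6 and 9.18 ± 19.9 CPM in the same heifers. Neither log2 fold change passed, at -0.92 ± 0.924 (SE, edgeR adjusted p = 0.729) and -0.96 ± 0.765 (adjusted p = 0.664). CIDR+24h replicate 4 decided both values: without it the log2 fold changes were -5.12 (edgeR adjusted p = 8.44e-05) and -4.04 (adjusted p = 3.11e-05). Both transcripts were chosen in these heifers among those highest at CIDR+12h, and the heifer left out was the 1 against a drop. These p-values are therefore no separate evidence. With that heifer kept, both passed with voom, with weights (adjusted p = 0.011 and 0.00865) and without (adjusted p = 0.0343 and 0.039). The same choice of transcripts limits these values. edgeR called 0 of 16940 transcripts, with 1500 at an unadjusted p under 0.05, where 847 were expected by chance. Leaving out a heifer moved this to 798 (CIDR+24h replicate 2), 858 (CIDR+24h replicate 6) or 2461 (CIDR+24h replicate 5). The groups of 38 transcripts did not overlap, against 36.7 expected by chance. DESeq2 called 11, voom with quality weights 2016 and voom without weights 12. Without CIDR+24h replicate 4, edgeR called 102, of which 95 were lower at CIDR+24h.

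Onset of oestrus was compared with CIDR+24h, and no transcript was called by edgeR. ENSBTAT00000010727 had 29.2 ± 26 CPM at Oestrus (SD, n = 4) against 7.5 ± 2.3 CPM at CIDR+24h (n = 6), a log2 difference of 1.96 ± 0.374 (SE, edgeR adjusted p = 0.134). ENSBTAT00000052651 had 21.3 ± 19.3 against 5.73 ± 1.62 CPM, a log2 difference of 1.89 ± 0.384 (adjusted p = 0.165). Both passed the 6-stage test with adjusted p of 0.0314 and 0.0378, and this call held in 22 of 30 omissions of single heifers for the first and in 9 of 30 for the second. Their high means at Oestrus came from replicates 3 and 4, which are also the 2 Oestrus heifers with 2-digit animal numbers. ENSBTAT00000010727 had 34.49 and 63.98 CPM in these, and 9.094 and 9.409 CPM in replicates 1 and 2. ENSBTAT00000052651 followed it, with 25.14 and 47.03 CPM in replicates 3 and 4, and 5.565 and 7.354 CPM in replicates 1 and 2. The 2 transcripts are therefore not separate findings, and whether they share reads was not tested. Without the 3 heifers with 2-digit numbers the log2 difference of ENSBTAT00000010727 was 0.32.

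In the same comparison, 3277 transcripts had an unadjusted p under 0.05, 1722 higher and 1555 lower at Oestrus, where 847 were expected. This number was 1559 without Oestrus replicate 4 and 1479 without the heifers with 2-digit numbers. The groups did not overlap in 792 transcripts, against 161 expected by chance (0.952% of transcripts for groups of these sizes), and 7 of all 210 splits of these heifers gave as many (exact permutation p = 0.0333, adjusted p = 0.233 over the 7 comparisons). DESeq2 called 119 transcripts, voom with quality weights 2202 and voom without weights 0. In the weighted fit, Oestrus replicates 3 and 4 had weights of 2.34 and 1.66, against 0.796 and 0.461 for replicates 1 and 2. The smallest edgeR adjusted p was 0.134.

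**Figure D2:**
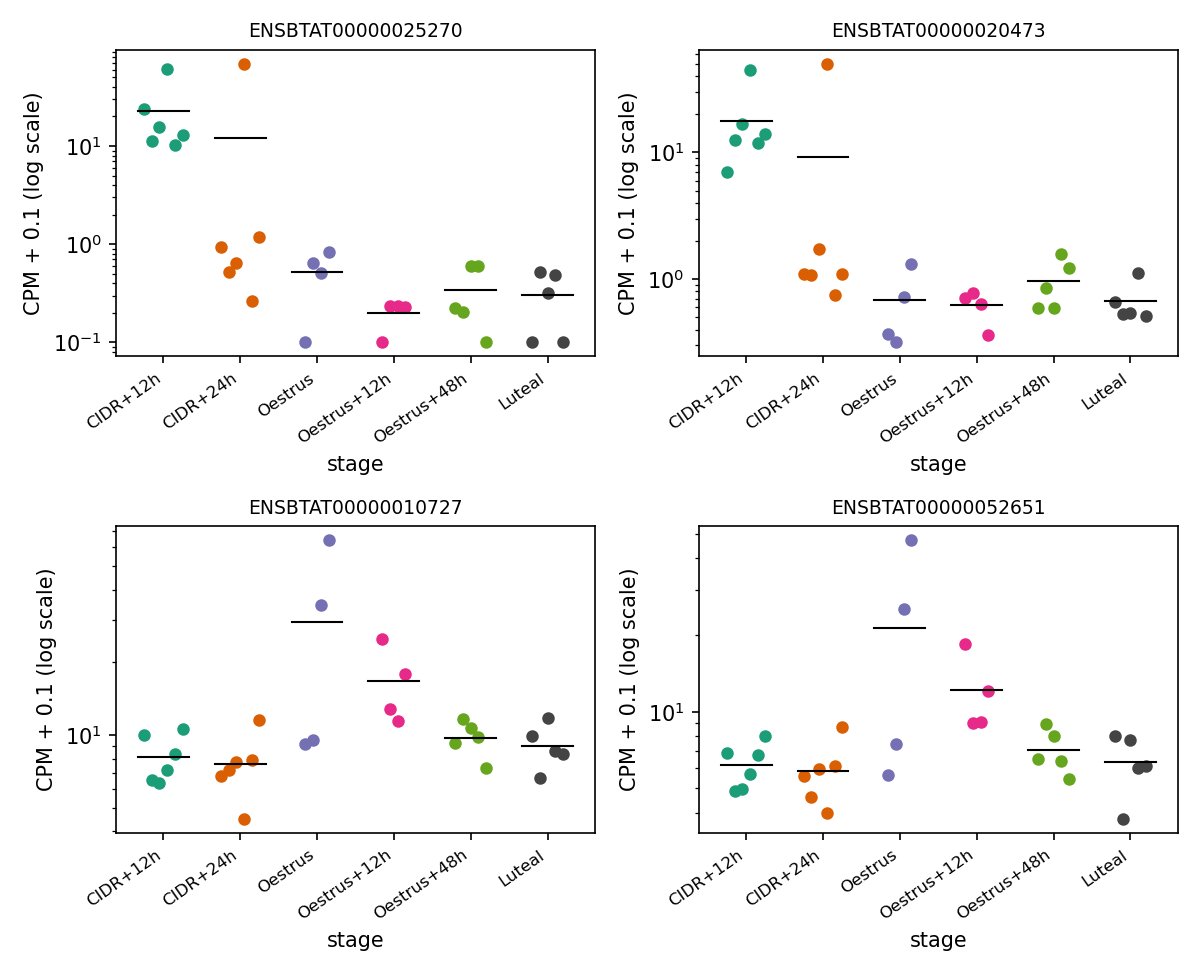
CPM plus 0.1 of 4 transcripts per heifer (points, log y axis) by stage (x axis), with a line at each stage mean. ENSBTAT00000025270 and ENSBTAT00000020473 are high in the CIDR+12h heifers and in 1 CIDR+24h heifer, and ENSBTAT00000010727 and ENSBTAT00000052651 are highest in 2 of the 4 Oestrus heifers.

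Levels 12 h after onset of oestrus were compared with those at onset. ENSBTAT00000010727 was at 16.7 ± 6.15 CPM at Oestrus+12h (SD, n = 4) and ENSBTAT00000052651 at 12.1 ± 4.38 CPM, both between their levels at Oestrus and at Oestrus+48h. The log2 differences from Oestrus were -0.81 ± 0.412 and -0.82 ± 0.424 (SE, edgeR adjusted p = 0.999 for each). The direction turned without the heifers with 2-digit numbers, to 0.87 and 0.92, and without Oestrus replicate 4 the values were -0.07 and -0.06. No transcript was called by edgeR, 554 had an unadjusted p under 0.05, and DESeq2 called 1. Both voom fits called 0. The unadjusted count ranged from 287 without Oestrus replicate 4 to 1236 without Oestrus replicate 2, with 1076 without Oestrus+12h replicate 1 and 367 without Oestrus+12h replicate 4. Groups did not overlap in 360 transcripts, against 484 expected by chance.

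From 12 h to 48 h after onset, ENSBTAT00000010727 was at 9.64 ± 1.65 CPM at Oestrus+48h (SD, n = 5), a log2 difference of -0.79 ± 0.391 (SE, edgeR adjusted p = 0.896). edgeR called 0 transcripts, 915 had an unadjusted p under 0.05, DESeq2 called 1 and both voom fits 0. The groups of 277 transcripts did not overlap, against 269 expected by chance. The unadjusted count was 430 without Oestrus+48h replicate 3 and 1453 without Oestrus+48h replicate 2.

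The luteal stage was compared with 48 h after onset. The 31 transcripts high at CIDR+12h were low in both, at a median of 0.476 ± 0.0649 CPM at Luteal (SD, n = 5) and 0.622 ± 0.0851 CPM at Oestrus+48h (n = 5). edgeR called 0 transcripts, 802 had an unadjusted p under 0.05, DESeq2 called 3 and both voom fits 0. Non-overlapping groups were found for 127 transcripts, against 134 expected by chance. Without Oestrus+48h replicate 3 the unadjusted count was 432.

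Oestrus was compared with the luteal stage as the 2 ends of the cycle's hormonal course, high oestrogen against high progesterone in general knowledge of the cycle, with no hormone measured here. ENSBTAT00000010727 was at 29.2 ± 26 CPM at Oestrus (SD, n = 4) and 8.95 ± 1.92 CPM at Luteal (n = 5), a log2 difference of 1.71 ± 0.393 (SE, edgeR adjusted p = 0.654). It was 0.99 without Oestrus replicate 4 and 0.07 without the heifers with 2-digit numbers, and its adjusted p was 0.0379 with DESeq2 and 0.0373 with voom quality weights. edgeR called 0 transcripts, 1227 had an unadjusted p under 0.05, DESeq2 called 11, voom with quality weights 421 and voom without weights 0. The unadjusted count was 489 without Oestrus replicate 4, 817 without Oestrus replicate 3, 812 without Luteal replicate 5, 2446 without Oestrus replicate 2, 2325 without Luteal replicate 3 and 273 without the heifers with 2-digit numbers. Groups did not overlap in 199 transcripts, against 269 expected by chance.

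The stage 12 h after CIDR removal was compared with the luteal stage, when the ovary's own progesterone is high. ENSBTAT00000025270 was at 22.5 ± 19.5 CPM at CIDR+12h (SD, n = 6) and 0.206 ± 0.204 CPM at Luteal (n = 5), a log2 difference of 6.70 ± 1.4 (SE, edgeR adjusted p = 0.186). ENSBTAT00000020473 was at 17.7 ± 13.6 and 0.572 ± 0.261 CPM, a log2 difference of 4.91 ± 1.01 (adjusted p = 0.186). Every CIDR+12h heifer lay above every luteal heifer for both. Over the 31 transcripts, the ratio of stage means was 16.9 at the median and 7.31 at the lowest, with 1 transcript lacking any luteal count. CIDR+12h replicate 4 raised the CIDR+12h means, with a median of 45.2 CPM over the 31 against 7.03 to 12 CPM in the other CIDR+12h heifers. Without it the log2 differences of ENSBTAT00000025270 and ENSBTAT00000020473 were 6.10 and 4.38. edgeR called 0 transcripts in the joint fit, with 293 at an unadjusted p under 0.05 and 445 without the heifers with 2-digit numbers. Groups did not overlap in 114 transcripts, against 73.3 expected by chance, and 69 of all 462 splits gave as many (exact permutation p = 0.149). edgeR called 42 when only the 2 stages were fitted, 26 of them among the 31. In a fit added after seeing the data, it called 80 without CIDR+24h replicate 4, a heifer of neither stage, all higher at CIDR+12h and 30 of them among the 31. The 31 were chosen in the same heifers for a high mean at CIDR+12h, so these overlaps are no separate evidence. DESeq2 called 50, voom with quality weights 50 and voom without weights 29.

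The difference between heifers as a whole was compared with stage. The first principal component held 26.2% of the variance of log2 CPM and the second 22.1%, and stage explained 16.2% (permutation p = 0.48) and 22.1% (permutation p = 0.275) of the heifers' positions on them. In a permutational test of distances, stage accounted for 20.3% of the distances between heifers, where 17.2% is expected by chance (permutation p = 0.16). Without CIDR+24h replicate 5 the share was 23.7% (permutation p = 0.0469), the highest of 30 omissions of single heifers. That p was not adjusted for this choice, and the 17.2% is for all 30 heifers. In exact permutation tests of the 7 pairs of stages, the smallest p was 0.177, with an adjusted p of 0.455.

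**Figure D3:**
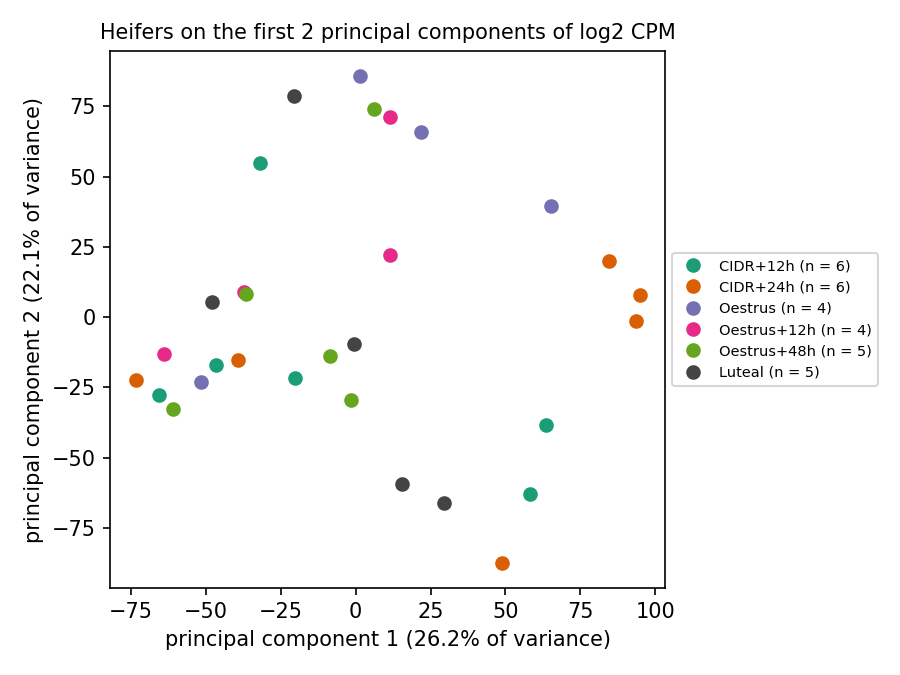
Heifers (points) on the first 2 principal components of log2 CPM, holding 26.2% (x axis) and 22.1% (y axis) of the variance, coloured by stage. Heifers of each stage are spread over the plane and overlap those of other stages.

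**Figure D4:**
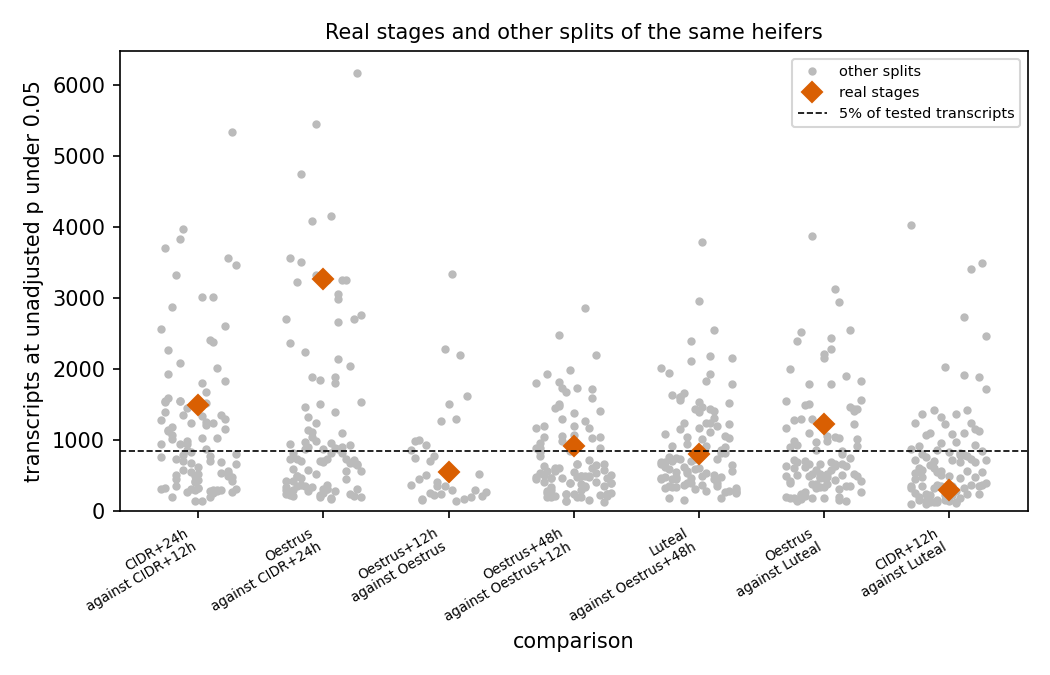
Number of transcripts at an unadjusted p under 0.05 (y axis) in each comparison (x axis) for the real stages (diamonds) and for other splits of the same heifers (grey points), with a dashed line at the 847 expected by chance. The real count for Oestrus against CIDR+24h is 3277 and the highest other split reaches 6170.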

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

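The test of a mixed-in RNA source was chosen after the result was seen, while the test of a wrong stage label was written before. Each value here stood apart from the rest of its stage by a gap that is large for the number of heifers. Of 54 groups of heifers examined, 9 had such a value, where chance gives about 1 in 20.

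CIDR+12h replicate 6 had the largest library, 19628122 counts, against 8819190 to 11075868 in the other CIDR+12h heifers. Luteal replicate 4 had 1.03 CPM of ENSBTAT00000020473, against 0.411 to 0.557 CPM in the other Luteal heifers. Oestrus+12h replicate 1 had 0 CPM of ENSBTAT00000025270, against 0.131 to 0.136 CPM in the other Oestrus+12h heifers, which is a count of 0 against 1 in each of the others, a gap set by whole counts.

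The remaining 6 values came from 2 heifers and the transcripts highest at CIDR+12h. CIDR+12h replicate 4 had a median of 45.2 CPM over the 31 transcripts, 60.9 CPM of ENSBTAT00000025270 and 44.8 CPM of ENSBTAT00000020473. CIDR+24h replicate 4 had a median of 46.1 CPM, 68.5 CPM of ENSBTAT00000025270 and 49.8 CPM of ENSBTAT00000020473. Both transcripts belong to the 31, so these are not separate findings.

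The pattern is that transcripts high in all CIDR+12h heifers were also high in 1 CIDR+24h heifer. Its median of 46.1 CPM was near that of CIDR+12h replicate 4 (45.2) and above the 7.03 to 12 CPM of the other CIDR+12h heifers. RNA of one source mixed into these libraries may account for this pattern, since the set would then keep 1 ratio between libraries. Against CIDR+12h replicate 4, the set's counts in the 6 other libraries had a median chi-square per degree of freedom of 8, more than counting noise, but 1.02 with an assumed 30% variation from library preparation, which was not measured. With that allowance, CIDR+24h replicate 4 had the lowest value, 0.283. CIDR+12h replicate 1 had the highest, 2.87, more than a single ratio would give, but it is 1 library of 6, so mixing stays open. Transcripts that change together could also keep 1 ratio, so this test cannot tell mixing from a shared response. Outside the set, the median correlation of CIDR+24h replicate 4 with CIDR+12h heifers minus that with other CIDR+24h heifers was -0.00448. By the rule written before this value was seen, a value below the median of the other 5, here -0.0021, counted against a wrong stage label. This value lay below it, but within 1 SD of the other 5 (0.0603) and inside their range of -0.0473 to 0.084. That margin was not in the rule, and with it a wrong label also stays open. A difference in the response at 12 h after CIDR removal, with 1 heifer slower than the rest at 24 h, is a biological hypothesis that was not tested.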

How the results depend on the processing

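The stage-wise test, voom without weights, 2 to 6 surrogate variables, the distance test with its settings and, for pairs, leaving out heifers of other stages were chosen after seeing the data. The 6-stage count of 39 was 292 with DESeq2, 14 with at least 10 CPM in at least 4 animals, 3878 with voom quality weights, 20 with 1 surrogate variable, 0 without the heifers with 2-digit numbers, 13 with voom without weights, and 18, 23, 7, 17 and 14 with 2, 3, 4, 5 and 6 surrogate variables. It was 41 and 39 with other size factors and 50 without a filter. Leaving out each heifer in turn gave 6 to 119, and 10 of 30 omissions kept it within 1.5 times.

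For the pairs, all 0 in the fit reported, DESeq2 called 11 (CIDR+24h against CIDR+12h), 119 (Oestrus against CIDR+24h), 1 (Oestrus+12h against Oestrus), 1 (Oestrus+48h against Oestrus+12h), 3 (Luteal against Oestrus+48h), 11 (Oestrus against Luteal) and 50 (CIDR+12h against Luteal). Quality weights called 2016, 2202, 0, 0, 0, 421 and 50 in that order. CIDR+12h replicate 6 had the largest weight in that fit, 4.07, against 0.595 to 1.05 in the rest of its stage. Voom without weights called 12 for CIDR+24h against CIDR+12h and 29 for CIDR+12h against Luteal. A fit of only the stages compared called 42 for CIDR+12h against Luteal and 0 for the other 6. With 2, 3, 4, 5 and 6 surrogate variables, CIDR+12h against Luteal gave 16, 5, 4, 13 and 14, and 5 surrogate variables gave 1 each for Oestrus against CIDR+24h, Oestrus+48h against Oestrus+12h and Luteal against Oestrus+48h. The stage-wise test called 1 for Oestrus against CIDR+24h. Leaving out single heifers gave 0 to 102 for CIDR+24h against CIDR+12h and 0 to 80 for CIDR+12h against Luteal, both highest without CIDR+24h replicate 4, and 0 to 4 for Oestrus against CIDR+24h, with 4 without Oestrus replicate 1 or replicate 2. The stage share of distances was 19 to 23.7%, the last without CIDR+24h replicate 5 (permutation p = 0.0469, not adjusted over the 30 omissions). The cause was not tested for these changes.

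The log2 differences of ENSBTAT00000010727 and ENSBTAT00000052651 for Oestrus+12h against Oestrus reversed without the heifers with 2-digit numbers, to 0.87 and 0.92, which leaves only Oestrus replicates 1 and 2 at Oestrus. No other log2 difference printed for a named transcript reversed in the alternatives run. ENSBTAT00000010727 (Oestrus against CIDR+24h) ranged from 1.25 without Oestrus replicate 4 to 2.25 without Oestrus replicate 2, and ENSBTAT00000052651 from 1.16 without Oestrus replicate 4 to 2.20 without Oestrus replicate 1. Without the heifers with 2-digit numbers they were 0.32 and 0.19. ENSBTAT00000020473 also lost its 6-stage call with 4, 5 and 6 surrogate variables (edgeR adjusted p = 0.121, 0.155 and 0.183), with a log2 difference of 4.72, 4.74 and 4.83 for CIDR+12h against Luteal. The tests of gene lists and their alternatives were not run, since no ID had a gene name. No paired analysis was possible because each heifer gave 1 sample and the labels carry no replicate numbers. Depth limits low transcripts: every heifer after CIDR+24h had a median under 1 CPM over the 31 transcripts, a few counts per library.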

Other observations

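The tests of composition and of counts by rank were chosen after the results were seen. A count by rank that needs no model was made for each stage: transcripts for which all heifers of the stage lay among the highest, or lowest, n + 1 of the 30, n being the stage's size. For CIDR+12h, all 6 heifers lay among the 7 highest in 64 transcripts, and 90 of all 593775 sets of 6 heifers gave as many (exact permutation p = 0.000152, adjusted p = 0.00365 over 24 counts), with up to 373 in another set. The allowance of 1 other heifer was set after CIDR+24h replicate 4 was seen among the highest, so the count restates that observation and does not exclude chance. With no allowance the count was 0, and all 593775 sets reached it, with up to 133 in another set. No other of the 24 counts, over both sides, all stages and both versions, passed, with the smallest unadjusted p of these at Oestrus, for 13 transcripts (exact permutation p = 0.0475, adjusted p = 0.551).

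Other splits of the same heifers put the counts of calls in proportion. In the 6-stage test, 8 of 100 splits gave 39 or more transcripts, the highest other 2946, so chance cannot be excluded. With sample quality weights the real split gave 3878, and 3 of 100 splits gave as many, with 5359 in the highest other. That share lies under the 0.05 threshold for this fit alone. It was not adjusted over the other counts tested by splits, so chance is not excluded here either. In the fit without weights, 2 splits gave 568 and 2946 transcripts, many times the real count, which points to a structure among the heifers. What that structure is was not tested.

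The pairs were all at 0 calls, which every split reaches: 100 of 100 for 6 comparisons and 35 of 35 for Oestrus+12h against Oestrus. The highest other splits gave 1676, 3777, 6, 1, 49, 0 and 558 in the order of the comparisons reported, from CIDR+24h against CIDR+12h to CIDR+12h against Luteal. At an unadjusted p under 0.05, the real counts of 1500, 3277, 554, 915, 802, 1227 and 293 were reached by 28, 9, 15, 32, 47, 28 and 75 splits, and the highest others were 5344, 6170, 3340, 2860, 3795, 3878 and 4026. Chance cannot be excluded for any of them.

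The absence of calls between pairs while heifers of a stage differed was weighed against technical causes. Library depth had its larger r with the first 2 components at -0.344 (rho = -0.389, permutation p = 0.063 and 0.034, adjusted p = 0.084 and 0.068 over 4 relations, r = -0.413 without the 2 heifers farthest from the median). By the rule set before this value was seen, an absolute r under 0.5 with both components counted against depth as a cause. The value met that rule, but was not beyond its spread from 0.5. That margin was not in the rule, and with it depth stays open. The share of the 10 most abundant transcripts had r = -0.639 with the second component (rho = -0.545, permutation p = 0.00014 and 0.0021, adjusted p = 0.00056 and 0.0084 over 4 relations, r = -0.553 without the 2 farthest), so it moves with the heifers and cannot be told apart from a difference in tissue. Numbers of heifers could limit the calls, since the lowest recovery of simulated 4-fold changes was 56.5%, and the same simulations did make calls. The simulated transcripts varied independently of each other, so this share may not hold for the real heifers. The labels give no sequencing batch, so no value within batches was available.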
